A study of Mus musculus with 4 samples.

How the data were processed

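Expression was measured on 4 Affymetrix arrays, 1 for each of 4 groups of mouse cells. Embryonic stem cells, labelled F/F for the control and Snai1 knockout for the other line, were grown as hanging drops and then in suspension to form embryoid bodies, which are aggregates of differentiating stem cells. The embryoid bodies were dissociated on day 4 and sorted with an antibody against Flk1, the receptor encoded by Kdr, into Flk1+ and Flk1- cells. Per the labels' protocols, cDNA was amplified from 50 ng of total RNA and labelled with biotin. The labels of the knockout Flk1- sample disagree on the day: its description gives day 4 and its source name gives day 5.

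The deposited values were log2 expression values for 45141 probe sets, and per the submitters' processing notes RMA and limma were used, with no version or role given in the sources used here. These log2 values were used as the authors deposited them, without a further normalization in the main setting. The 104 control probe sets were left out. Of the others, 28898 were paired with 1 gene, 551 with several genes, which were not named, and 15588 with no gene in the annotation used here. The probe sets with 1 gene covered 17098 genes, of which 16937 had an identifier in the reference gene table (161 did not), and 0 symbols changed. For a gene with several probe sets, the probe set with the highest mean over the 4 arrays was taken.

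A floor separated genes with signal from those without. The plan set it on olfactory, vomeronasal and trace amine receptor genes, which are silent in most tissues, but only 79 were named and at least 100 were needed. The planned fallback was therefore used, the 40th percentile of all genes on all arrays, which was 3.19 on the log2 scale. Above it on at least 1 array were 10955 genes, including 8 of the 79 receptor genes. A fold against a value below the floor is given as a lower bound, computed against the floor.

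With 1 array per group there was no spread between replicates, so no test was run and no p-value is given. The number of arrays limits the precision. Each comparison is a difference of log2 values on 2 arrays, counted where it was at least 1 in size (2-fold) and the gene was above the floor on at least 1 of those arrays. The 4 comparisons were knockout minus control in Flk1+ and in Flk1- cells, and Flk1+ minus Flk1- in control and in knockout cells. The difference of differences was the genotype difference in Flk1+ cells minus that in Flk1- cells. A model without an interaction was not fitted, since the interaction would have served as its error.

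Before the data were examined, 35 gene lists were fixed, with 10 genes each way per comparison and up to 4 members of a list that stood apart (2 of any other) as the rule for named genes. Snai1 and Kdr and the 10 genes furthest apart each way in both fractions were added by the same rule, and gene models without a proper name were passed over. A list was described by the median difference of its members above the floor and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. It stood apart at or below percentile 2.5 or at or above percentile 97.5. By chance 1.7 of the 34 lists with at least 5 members above the floor would do so in a comparison. The percentile describes these arrays and is no test of the genotype, and members of a list are not independent.

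The method was tested on simulated data made from the means of the 17098 genes with the spread seen in receptor genes (SD 0.0966). For the knockout minus control comparison in Flk1+ cells, the 2-fold rule recovered 50 of 50 genes given a log2 difference of 1.5 and 0 of 50 given 0.5, and it called 0 of 10280 genes given none. Of 200 random lists of 20 genes, 8 stood apart with no shift, and 100 of 100 did with a shift of 0.5. At the larger spread between probe sets of a gene (SD 0.170), a simulation added after seeing the data, the 2-fold rule recovered 50 of 50 genes given 1.5 and 0 of 50 given 0.5, and it called 1 of 10459 genes given none. Both drew independent, normal noise that was narrow against the 2-fold rule, so few calls without a difference followed from the setting. In the data, the gap between 2 probe sets of a gene was 2-fold or more in 0.983% of genes for knockout minus control in Flk1+ cells. The lists with no shift came from the same genes as the lists they were ranked among, so a share near 5% was given in advance. Neither simulation contains the spread between cultures or list members that vary together.

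The alternatives tried were size rules of 1.5-fold and 3-fold, a floor at the median, no floor, quantile normalization again, centring on the median of detected genes, cyclic loess (span 0.3, 3 rounds) and the mean of a gene's probe sets. For lists, unmatched random lists, the mean, the list without its farthest member and members of no other list were added. Values set to the floor and the omission of probe sets ending in _s_at or _x_at were chosen after seeing the data. So were 3 further gene lists for erythroid, endothelial and contractile genes, written when the 25 genes furthest apart each way and the members of the fixed lists had been looked at. The erythroid and contractile lists were therefore also tested without those genes. All 25 endothelial members above the floor were in a fixed list, so no such test was possible for them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.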

Results

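Gene expression was compared between control and Snai1 knockout cells that were sorted by Flk1 from embryoid bodies. There were 4 groups, control Flk1+, control Flk1-, knockout Flk1+ and knockout Flk1-, with 1 array each and therefore no replicates, so no difference below has a replicate check. The labels of the knockout Flk1- sample name both day 4 and day 5. On the arrays 10195 to 10302 genes were above the floor. Pairs of arrays correlated at r = 0.94 to 0.98 across 10955 genes, which are not independent replicates. The 3' minus 5' signal of the Gapdh control probe sets was 2.05, 1.76, 1.47 and 1.99 in control Flk1+, control Flk1-, knockout Flk1+ and knockout Flk1- cells.

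Snai1, a transcriptional repressor that acts on epithelial genes, had values of 2.56 in control Flk1+, 2.42 in control Flk1-, 1.88 in knockout Flk1+ and 1.94 in knockout Flk1- cells. All 4 values were below the floor of 3.19, so they do not check the genotype labels. Where its probe set lies relative to the deleted part of the gene is not given in the sources used here. Kdr, which encodes Flk1, was at 8.92 in control Flk1+ and 4.55 in control Flk1- cells, and at 9.03 and 3.88 in the corresponding knockout cells, as the sort labels say.

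Within Flk1+ cells, genes of pluripotent and epithelial cells were higher in the knockout, and embryonic globin genes, cardiac genes and mesenchymal genes were lower. Nanog, a pluripotency transcription factor, was at 5.41 in the knockout and 3.38 in the control, Dppa5a was at 6.68 and 4.67, and Sox2 was at least 2.87-fold higher. Cdh1, the epithelial cadherin, was at 7.84 against 6.05, and the claudins Cldn7 and Cldn6 were 1.55 and 1.54 higher on the log2 scale. The endoderm genes Cer1, a secreted Nodal and BMP antagonist, and Pga5 were 2.18 and 2.28 higher. The embryonic globin genes Hba-x and Hbb-bh1 were at least 3.77-fold and 5.17-fold lower, the cardiac troponin gene Tnnt2 was at 4.12 against 6.88, and the mesoderm transcription factor genes Hand1 and Foxf1 differed by -2.49 and -2.58.

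In these Flk1+ cells 93 genes were 2-fold or more higher and 104 lower in the knockout, among 10655 genes. With the arrays centred on the median of detected genes the split was 120 higher and 84 lower. Other genes at the top were Irs4, Nptx2, Slc7a3, Cited1, Fzd5 and Eras, from 2.08 to 2.15 higher, and Igfbp3, at least 2.61-fold higher. The probe sets of Irs4 ranged from 0.56 to 2.15 and those of Nptx2 from 0.86 to 2.14. Lower were also Actc1, the cardiac actin, by at least 3.89-fold, Col1a1 by -2.55 and the smooth muscle actin Acta2 by -2.42. Dnlz had a difference of -2.57, but its probe sets ranged from -2.57 to 0.31. Without the probe sets ending in _s_at or _x_at, an alternative chosen after seeing the data, Dnlz had a difference of 0.28.

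Of the 34 lists, 17 stood apart in Flk1+ cells, 8 higher and 9 lower in the knockout. The primed epiblast list, genes of the epiblast after implantation, had a median difference of 0.83 (interquartile range 0.24 to 1.11), with 14 of 16 members higher, led by Cldn6 and Fgf5 (1.52). The epithelial list had a median of 0.59 with 33 of 40 members higher, and the pluripotency list had a median of 0.27 with 20 of 25 higher. Over the alternatives run, the pluripotency value ranged from 0.17 to 0.63, the mean over members, and the epithelial value from 0.35 to 0.65. Nodal and activin targets had a median of 0.29, and FGF and ERK feedback genes, with Spry4 at 0.93, had a median of 0.19. Endoderm, paraxial mesoderm and the amino acid and ER stress response had medians of 0.13, 0.20 and 0.14.

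Lower in knockout Flk1+ cells were BMP targets, with a median of -0.79 and Msx1, Msx2 and Smad6 at -1.74, -1.65 and -1.62. Of its 15 members, 8 were lower and 7 higher. Over the members that no other list holds, the BMP target median was 0.028. The lateral plate and cardiac mesoderm list had a median of -0.58, with 20 of 27 members lower. Cholesterol synthesis had a median of -0.52 (-0.28 with the mean of the probe sets of a gene), with Nsdhl, Msmo1, Mvk and Dhcr7 from -0.71 to -0.61, although the probe sets of Mvk ranged from -0.62 to 0.18 and those of Msmo1 from -0.65 to -0.019. The mesenchymal list had a median of -0.34, with 22 of 30 members lower, and Hox genes had one of -0.35 (-0.085 with the floor at the median of all values). Fibroblast (feeder cell) markers, a check for carried-over feeder cells that shares Col1a1 and Col3a1 with the mesenchymal list, had a median of -0.25 over 8 members. Wnt targets had a median of -0.27, the primitive streak and nascent mesoderm list -0.24, and S phase genes -0.21 (-0.12 after quantile normalization or cyclic loess). The hemato-endothelial list had a median of -0.11 at percentile 6.42 and did not stand apart. Of the 17 calls, 9 held under every alternative run, and those of primitive streak, paraxial mesoderm, endoderm, fibroblast, Wnt target, BMP target, S phase and Hox genes were each lost under at least 1. The call of Nodal and activin targets, among those that held, was run under 11 alternatives and not 12. Too few of its members were in no other list, so its overlap with other lists was not checked.

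**Figure D1:**
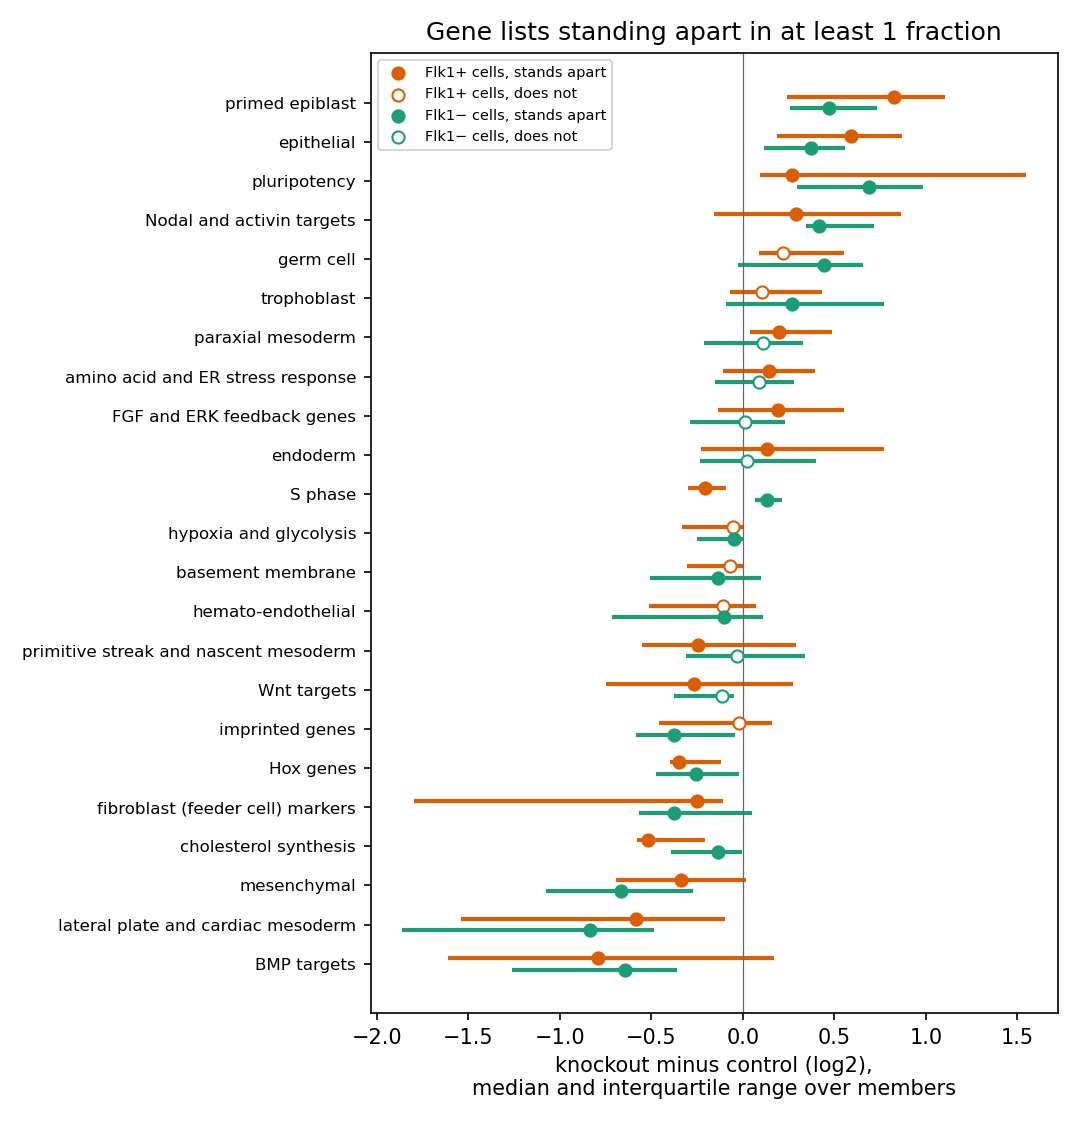
Median difference between knockout and control on the log2 scale, with the interquartile range over members as a line, for the gene lists that stood apart in at least 1 fraction; orange stands for Flk1+ and green for Flk1- cells, filled points stood apart and open points did not. The lateral plate and cardiac list lies at -0.58 in Flk1+ and -0.83 in Flk1- cells, and the primed epiblast list at 0.83 and 0.47.

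Within Flk1- cells, the genes furthest apart were embryonic and alpha globin genes and cardiac genes, all lower in the knockout. The embryonic globin gene Hba-x was at 2.01 in the knockout and 9.77 in the control, at least 95.9-fold lower, and Hbb-bh1 and Hbb-y were at least 106-fold and 48.9-fold lower. The alpha globin gene Hba-a1 differed by -5.15, with its probe sets ranging from -6.51 to -3.66. Klf1, an erythroid transcription factor, was at least 2.31-fold lower. Tnnt2 was at 3.38 against 7.39, Actc1 was at least 9.41-fold lower, and Hand1, Unc5c, Myl4 and Dlk1 differed by -3.21, -3.02, -2.81 and -2.79.

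Higher in knockout Flk1- cells were Mymx by 1.95, the forebrain and pituitary gene Hesx1 by 1.84, the pluripotency factor Esrrb by 1.72 and the Nodal antagonist Lefty1 by 1.60. In all, 41 genes were 2-fold or more higher and 100 lower among 10533 genes. The probe sets of Esrrb ranged from -0.08 to 1.72, and Foxq1, with a difference of 1.42, had one of -0.10 without the probe sets ending in _s_at or _x_at. At the 1.5-fold rule the split was 313 higher and 267 lower.

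In Flk1- cells 17 of the 34 lists stood apart, 7 higher and 10 lower in the knockout. The pluripotency list had a median of 0.69 with 23 of 25 members higher, the primed epiblast list 0.47 with 15 of 16, the epithelial list 0.37 with 34 of 40, and Nodal and activin targets 0.42 with 10 of 11. The germ cell list had a median of 0.44, with Tfap2c and Dppa3 at 0.96 and 0.74, and the trophoblast list, which shares Tfap2c, had one of 0.27. Over the members that no other list holds the germ cell median was 0.077. S phase genes had a median of 0.13, with 26 of 27 members higher, and one of 0.079 after centring on the median.

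Lower in knockout Flk1- cells were the lateral plate and cardiac mesoderm list, with a median of -0.83 and 25 of 27 members lower, and the mesenchymal list, with a median of -0.66 and 28 of 30 lower. Acta2, Cdh11, Col1a1 and Zeb1 led the mesenchymal list, with Zeb1 at -1.33 and its probe sets from -1.33 to -0.13. BMP targets had a median of -0.64 with 14 of 15 lower, including Bmp4 at -2.06. The imprinted genes had a median of -0.38, with Dlk1, Cdkn1c and Plagl1 at -2.79, -1.65 and -1.48. Fibroblast (feeder cell) markers had a median of -0.38 (-0.0081 with no floor), and Hox genes one of -0.25 (-0.0096 with values below the floor set to the floor). Basement membrane genes had a median of -0.14, cholesterol synthesis -0.14, the hemato-endothelial list -0.10, and hypoxia and glycolysis -0.05. The hemato-endothelial list also holds globin and erythroid genes, and 25 endothelial genes without these, a list chosen after seeing the data, had a median of -0.024 at percentile 20.2 and did not stand apart. Of the 17 calls, 11 held under every alternative run, and those of hemato-endothelial, trophoblast, germ cell, fibroblast, hypoxia and Hox genes were each lost under at least 1. Nodal and activin targets were among those that held, but could not be run over members of no other list here either.

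Lists that stood apart for genotype in neither fraction are given by their medians in Flk1+ and Flk1- cells. They were neuroectoderm (0.03 and 0.10), neural crest and surface ectoderm (0.10 and -0.11), Notch targets (0.00 and 0.12), immediate early genes (-0.14 and -0.06), heat shock genes (-0.02 and 0.06), and p53 targets (0.00 and 0.00). The medians were -0.06 and 0.05 for G2 and M phase, 0.02 and 0.02 for ribosomal proteins, -0.11 and 0.08 for mitochondrial respiration, -0.12 and -0.04 for X and Y dosage, and -0.02 and 0.01 for reference genes. The X and Y dosage list pools Xist with other X genes and Y genes, which need not go the same way. Its median therefore does not check the sex chromosome content of the lines. No member of the list of miR-200 family hosts was named on the array, so this list has 0 members and no value.

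The genotype differences of the fractions were set side by side, which share no array. Both fractions of a genotype were sorted from embryoid bodies of that line and may come from the same culture. A difference between lines or cultures would enter both fractions, and the values for independent lists make no allowance for it. Genes 2-fold or more higher in both fractions numbered 16, against 0.276 for independent lists, and 38 were lower in both, against 0.863. They included Lefty1, Nptx2, Igfbp3, Tnnt1, Eras and Ascl2 on the higher side, and Hba-x, Hbb-bh1, Actc1, Tnnt2, Foxf1, Hand1, Unc5c, Acta2 and Ttr on the lower side. No gene was 2-fold apart in opposite directions (0 genes), against 1.13 for independent lists. Of 184 genes 2-fold apart in Flk1+ cells, 169 had the same sign in Flk1- cells. Across 10955 genes the differences correlated at r = 0.39 and rho = 0.17.

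**Figure D2:**
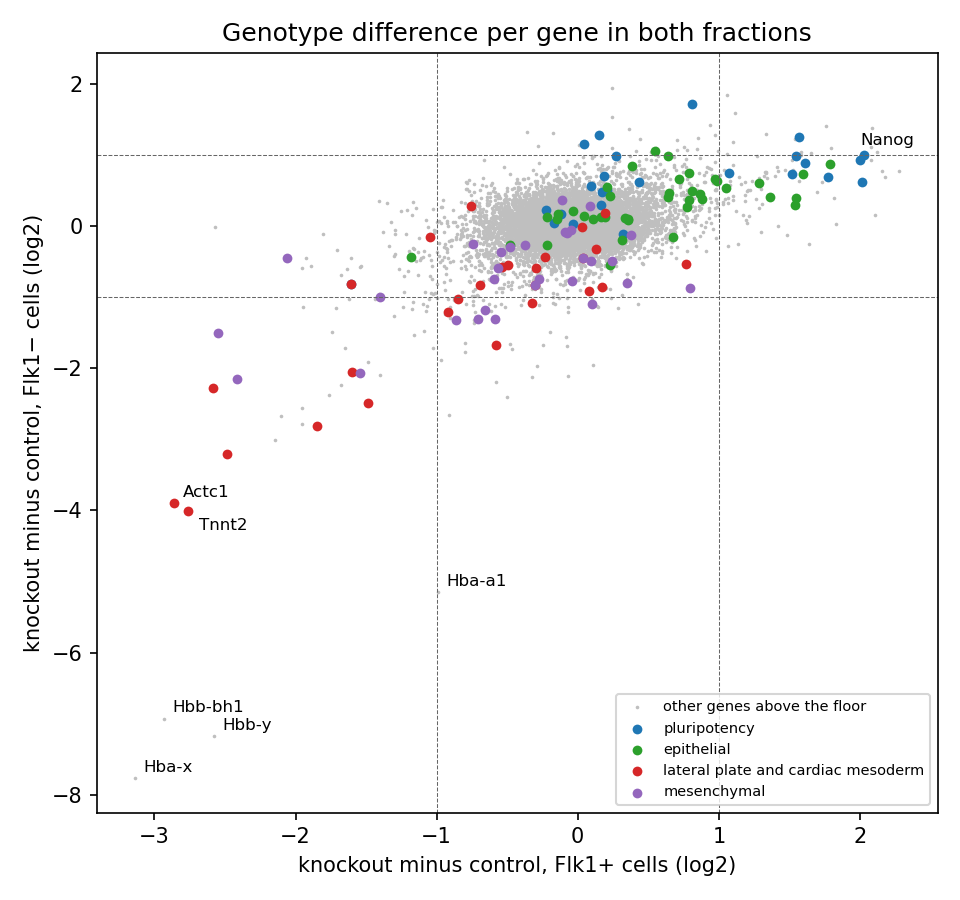
Knockout minus control on the log2 scale in Flk1+ cells (horizontal axis) and Flk1- cells (vertical axis), 1 point per gene above the floor, with 4 gene lists in colour and dashed lines at 2-fold. Values below the floor were plotted as deposited. Tnnt2 lies at -2.76 and -4.01, and Nanog is 2.03 higher in Flk1+ cells.

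The difference of differences was at least 1 in size for 82 genes in the positive and 91 in the negative direction. Globin genes led the positive side in the deposited values, where they were further apart in Flk1- cells. The embryonic globin genes Hba-x and Hbb-y were below the floor in both knockout fractions, and with values below the floor set to the floor they were at 4.67 and 4.50. Set in this way, both values only repeat the sort difference in control cells with its sign turned, so they do not rank the fractions. The alpha globin gene Hba-a1, above the floor on all 4 arrays, was at 4.16. It was at 3.79 and 3.88 in knockout Flk1+ and Flk1- cells, not far above the floor. Its value was close to the control sort difference of -4.25 with the sign turned, so it too may not rank the fractions. Cited1 and Igfbp5 were at 1.95 and 1.89. Adam12 was at 0.83 and the collagen gene Col3a1 at -1.80 with values below the floor set to the floor. Ackr3, a chemokine receptor, was at -1.77. With the arrays centred on the median the split was 119 and 52, and with cyclic loess it was 102 and 73.

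Of the 34 lists, 12 stood apart in the difference of differences, 9 on the positive side. The lateral plate and cardiac list had a median of 0.45, the mesenchymal list 0.31, the imprinted genes 0.30, endoderm 0.29 and the epithelial list 0.23. S phase genes had a median of -0.31, with Hells, Clspn, Ccne2 and Cdt1 from -0.95 to -0.61 (the probe sets of Hells ranged from -0.95 to 0.085), and mitochondrial respiration had one of -0.19. Fibroblast (feeder cell) markers were at -0.32, but their percentile was 24.6 over members that no other list holds. The calls of mesenchymal, paraxial mesoderm, amino acid response and mitochondrial genes were also each lost under at least 1 alternative.

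The sort comparison within control cells asked which genes go with Flk1. Kdr was 4.38 higher in Flk1+ cells, and the endothelial transcription factor genes Fli1, Sox18, Erg and Etv2 were at least 4.81-fold, 7.04-fold, 9.68-fold and 11.7-fold higher. Ctla2a, Hapln1 and Arap3 were 3.67, 3.60 and 3.22 higher, and the probe sets of Arap3 ranged from 1.35 to 3.22. Lower in control Flk1+ cells were the embryonic globin genes, with Hba-x at 5.11 against 9.77, and the pluripotency genes, with Nanog at 3.38 against 6.57 and Dppa5a at 4.67 against 8.21. Cdh1 and Epcam, both epithelial adhesion genes, differed by -1.71 and -1.48.

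In control cells 127 genes were 2-fold or more higher and 160 lower in Flk1+ than in Flk1- cells among 10622 genes, and 21 of 34 lists stood apart. Of these 21 calls, 10 held under every alternative run. The hemato-endothelial list had a median of 0.61, with 29 of 39 members higher and 16 of them 2-fold or more. The mesenchymal list had a median of 0.45 with 27 of 30 higher, basement membrane genes 0.33 with Col4a2 at 1.65 (a call lost over members that no other list holds), and the primitive streak list 0.27 with Mixl1 at 1.26. The pluripotency list had a median of -1.48 with 22 of 25 lower, the primed epiblast list -0.73, the epithelial list -0.62 with 35 of 40 lower, p53 targets -0.37 and hypoxia and glycolysis -0.23.

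In knockout cells Kdr was 5.15 higher in the Flk1+ fraction, and Adam12, Fli1, Hapln1 and Etv2 were at least 11.2-fold, 4.90-fold, 12.8-fold and 12.2-fold higher. Lmo2, a hematopoietic and endothelial cofactor, was at 7.07 against 3.30. Mageb16, Esrrb and Fbxo15 were at least 7.37-fold, 5.94-fold and 4.98-fold lower in Flk1+ cells, and Dppa3 was at 4.66 against 7.68. The probe sets of Esrrb ranged from -3.05 to 0.039. The embryonic globin gene Hbb-bh1, chosen here after its values were seen, was at 2.63 and 2.98 in knockout Flk1+ and Flk1- cells, both below the floor.

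In knockout cells 173 genes were 2-fold or more higher and 232 lower in Flk1+ cells among 10688 genes, and 20 of 34 lists stood apart. Of these 20 calls, 8 held under every alternative run, those of the lists given below. With the arrays centred on the median the split was 223 higher and 147 lower, and this centring moved the median difference of all detected genes from -0.07 to 0.09. The mesenchymal list had a median of 0.75 with 28 of 30 members higher, the lateral plate and cardiac list 0.49 and the hemato-endothelial list 0.38. The pluripotency list had a median of -1.75, the primed epiblast list -0.57, S phase genes -0.44, cholesterol synthesis -0.41 and the epithelial list -0.39. Genes 2-fold apart by sort in both genotypes numbered 77 higher and 81 lower, against 1.88 and 3.30 for independent lists, and the sort differences correlated at r = 0.62 and rho = 0.46 across genes.

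**Figure D3:**
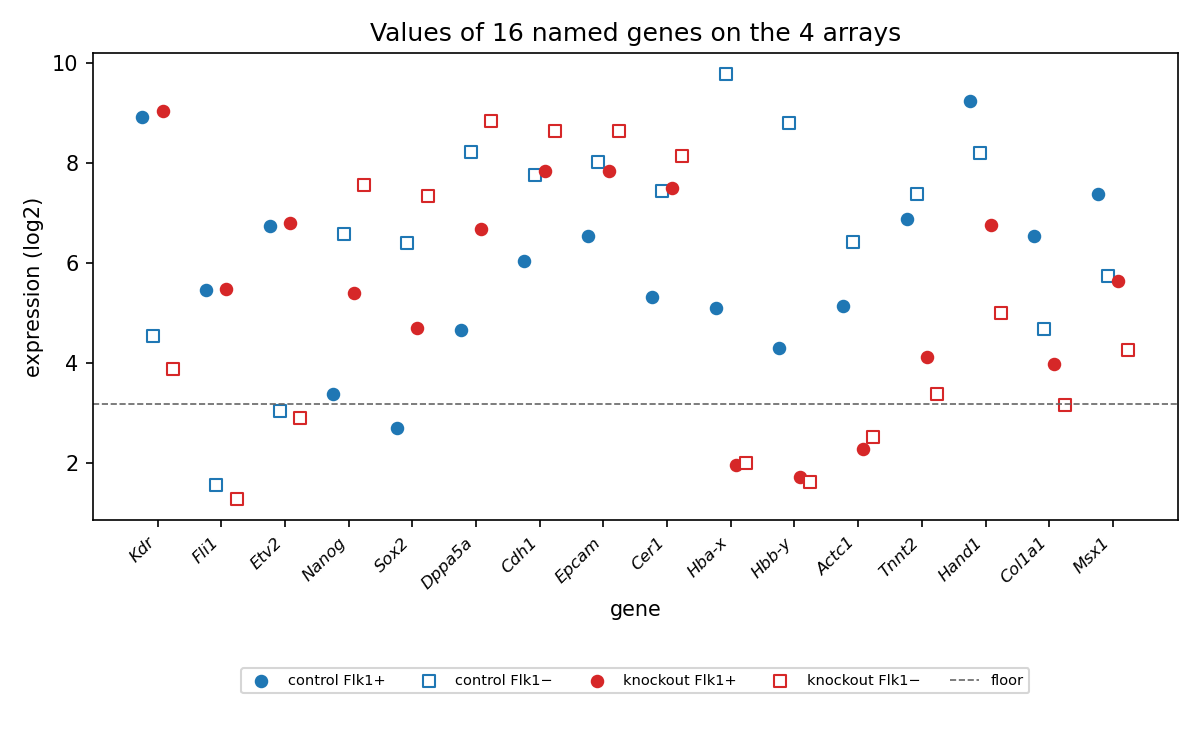
Expression on the log2 scale of 16 named genes on the 4 arrays, with filled circles for Flk1+ and open squares for Flk1- cells, blue for control and red for knockout, and the floor as a dashed line. Kdr separates the sorted fractions in both genotypes (8.92 and 9.03 against 4.55 and 3.88), and Hba-x is above the floor only on the control arrays.

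Without replicates, spread could be read only from silent genes and from probe sets of a gene. Among the 79 receptor genes the difference had an SD of 0.13 to 0.17 over the 4 comparisons, and 0 genes were 2-fold apart. The gap between 2 probe sets of a gene had an SD of 0.29 to 0.42. It holds the spread of 2 differences, and per probe set the SD was 0.21 to 0.30. This gap was 2-fold or more in 0.983%, 0.660%, 0.904% and 2.49% of genes for knockout minus control in Flk1+ and in Flk1- cells and for the sort in control and in knockout cells, and 1.85%, 1.34%, 2.70% and 3.79% of genes were 2-fold apart in these comparisons. The shares for gaps and for single differences are therefore not on the same scale. Neither the spread of receptor genes nor that between probe sets contains the spread between cultures.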

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

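Cyclic loess and the S phase, epithelial, pluripotency and cardiac lists were planned, but their use against the explanations below, and the other tests in this part, were chosen after the results were seen. S phase genes went opposite ways in the fractions, with a median of -0.21 in knockout Flk1+ and 0.13 in knockout Flk1- cells (after cyclic loess -0.12 and 0.098), so that the difference of differences was -0.31; with 1 array per group this difference was not tested. An intensity-dependent trend between arrays could give such a pattern. After cyclic loess the difference of differences was still -0.22, at percentile 0.01 of matched random lists, which argues against that trend as the whole cause. In the Flk1+ pair, whose labels give the same day, the list was below matched random lists under all 4 normalizations, with -0.12 as the value nearest to random lists, which argues against the day of the knockout Flk1- sample as the whole cause. That day for the value of 0.13 in Flk1- cells, and a difference in the growth of the cultures, stay open as untested.

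Epithelial and pluripotency genes were higher in knockout than control Flk1+ cells, and both groups were lower in Flk1+ than Flk1- cells, so carry-over of Flk1- cells into the knockout Flk1+ fraction may be a source. Shares of Flk1- cells were computed only for members at least 2-fold higher in knockout Flk1- than control Flk1+ cells. The 10 of 16 primed epiblast members would need a median share of 0.424 (quartiles 0.245 and 0.547), but carry-over was not tested for that list. The shares that 20 of 40 epithelial members would need had a lower quartile of 0.309 and a median of 0.453. Both were above the upper quartile of 0.141 for 16 of 25 pluripotency members. The same share of cells with the makeup of the knockout Flk1- array would therefore not account for both epithelial and pluripotency genes. The labels of that array disagree on the day, so it may not stand for the cells that could be carried over. The Flk1+ markers were the 16 hemato-endothelial members at least 2-fold higher in control Flk1+ than control Flk1- cells. They were picked for high values in control Flk1+ cells, which are also subtracted here, so the choice alone favours a negative difference. The share of 0.309 would give these markers a difference of -0.44, just below their lower quartile of -0.37. That quartile is a spread over genes and no error bound, so the markers do not decide. Other genes higher in control Flk1- cells, with and without pluripotency genes, gave median upper limits of 0.225 and 0.268 where at least 4-fold apart, below 0.309. Where at least 2-fold apart they gave 0.458 and 0.492, above it. Earlier forms of the test that rested on these limits gave different answers. Carry-over for epithelial genes is thus not decided, and a part of the Flk1- cells rich in epithelial genes stays open. For pluripotency genes the share needed was 0.103 at the median, and the markers would then differ by -0.13 and differed by -0.14 (quartiles -0.37 and 0.07), so there carry-over and genotype cannot be told apart, because the fall is smaller than the spread of the markers. After cyclic loess the epithelial median was 0.60 and still above matched random lists, which argues against the narrower signal range of the knockout Flk1+ array as the whole cause.

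Embryonic globin, erythroid and cardiac genes were lower in knockout than control Flk1- cells. The source name would make the knockout Flk1- sample the later one, and no arrays here compare days within a genotype. Which way a day effect would go is therefore not known from these data. The conflicting day or sequence shared between globin genes could each be a source. In the Flk1+ pair, whose labels give the same day, the lateral plate and cardiac list also had a median of -0.58, and 5 globin genes, with values below the floor set to the floor, one of -1.12 (quartiles -1.91 and -0.99), both below matched random lists, which argues against the day as the whole cause for cardiac and globin genes, Hbb-b2 excepted at 0.11. Erythroid genes outside the globin family had a median of 0.054 there, inside matched random lists, and the whole erythroid list one of -0.0064, so for these genes the day and the genotype cannot be told apart, because they were already at -0.63 in control Flk1+ against Flk1- cells. In Flk1- cells they had a median of -0.52, with 15 of 18 members lower, and one of -0.47 over the 17 not named by the rule, both below matched random lists. Both versions hold genes whose values had been looked at before the list was written. Over the 13 members that had not been, the median was -0.11, with 10 lower and at percentile 2.98, just inside random lists (difference of differences 0.46, percentile 100). Whether shared sequence is the whole cause is therefore not decided. How far each globin gene differed on its own, another share of Flk1- cells in control Flk1+ cells, and fewer erythroid and cardiac cells or lower expression per cell in the knockout, stay open as untested.

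Probe sets with no gene in the annotation were outside the comparisons. Of those above the floor, 41 were 2-fold or more higher and 46 lower in the knockout in Flk1+ cells, and 12 and 56 in Flk1- cells. A pair of these was higher in the knockout, by 1.40 and 1.07 on the log2 scale in Flk1- cells, and at 3.52 and 4.87 in knockout Flk1+ cells with both control values below the floor. Another pair was lower in both, from 6.06 to 3.53 and from 6.15 to below the floor in Flk1+ cells, and from 9.82 to 3.59 and from 9.74 to below the floor in Flk1- cells. The control values of this pair were close to those of Hbb-bh1, 5.56 in Flk1+ and 9.91 in Flk1- cells. Probe sets without a gene here may measure genes already named, which was not examined.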

How the results depend on the processing

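Omitting probe sets ending in _s_at or _x_at and setting low values to the floor were chosen after seeing the data. Under the floor and normalization alternatives and both of these, each total of 2-fold genes was within 1.5 times its main value, and so was that with the mean of probe sets except for the difference of differences, 113 genes against 173. By direction, centring on the median moved lower genes in the knockout sort from 232 to 147 and negative differences of differences from 91 to 52, and the mean of probe sets moved the latter to 56, higher genes in Flk1- cells from 41 to 27 and genes higher in both fractions from 16 to 9. Correlations across genes moved by under 0.1. The size rule changed every count. At 1.5-fold and 3-fold they were 818 and 59 (Flk1+), 580 and 42 (Flk1-), 1598 and 108 (sort, knockout), 876 and 102 (sort, control), 1192 and 25 (difference of differences) and 216 and 17 (both fractions). The number of lists that stood apart was within 1.5 times the main number under every alternative run for it.

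Of 87 list calls, 45 held under every alternative run, and the value of 65 moved by over 1.5 times under at least 1. Across lists and alternatives, 1860 values kept their call or their lack of one, 96 lost and 75 gained a call. A change of sign was counted only for lists and genes called in the main setting. Among lists there were 4: BMP targets in Flk1+ cells (0.028) and germ cell genes in the knockout sort (0.25), both over members of no other list, trophoblast genes in the control sort with no floor (0.053), and the amino acid and ER stress response in the knockout sort by the mean (-0.0040). Among named genes 4140 values kept their call or their lack of one, 94 lost and 26 gained a call, and 3 called values changed sign, all without probe sets ending in _s_at or _x_at: Dnlz (0.28) in Flk1+ cells, Foxq1 (-0.10) in Flk1- cells and Dnlz (0.38) in the difference of differences. These rest on other probe sets of the gene; otherwise the cause was not tested. That setting gave no value in 25 cases, 19 with no probe set left and 6, Acta2 among them, with only probe sets below the floor. Values near the floor of 3.19 limit what can be read from low genes such as Snai1.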

Other observations

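Both gene lists in this part, and the tests of them, were chosen after the data were seen, while the normalizations named were planned. Genes of the contractile apparatus were lower in the knockout as a group, with 21 of 26 members lower in Flk1+ and 23 of 26 in Flk1- cells and medians of -0.31 and -0.47. Ahnak, which had been put on the list and is no contractile gene, was left out of these values. To see whether this went beyond genes already looked at when the list was written, the other 20 members were taken alone, and their medians were -0.27 and -0.31, with 15 and 17 lower, both below matched random lists. This is consistent with a wider difference in contractile genes, as a hypothesis. Pdlim3, Csrp1 and Myh10 were at -1.20, -0.70 and -0.65 in Flk1+ cells.

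Of 25 endothelial genes, 16 were lower and 9 higher in knockout than control Flk1+ cells. Ets1 and Tek were at -1.17 and -0.86, and Etv2, Fli1 and Gata2 at 0.06, 0.03 and 0.15, genes chosen after their values were seen. Tie1, chosen in the same way, went from 3.31, near the floor, to below it. The hypothesis that these genes may be lower as a group did not hold under every normalization. Their median was -0.17 at percentile 1.60 with the authors' values and -0.11 at percentile 1.54 after centring on the median, both below matched random lists, but -0.10 at percentile 6.70 after quantile normalization and -0.083 at percentile 11.9 after cyclic loess, both inside them.

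The signal in control Flk1+ cells was 3.93% of that in control Flk1- cells for Hba-x, 4.43% for Hbb-y, 4.90% for Hbb-bh1 and 5.26% for Hba-a1. It was 28.5% for Hbb-b2, which was at 4.59 in control Flk1+ cells and at 4.70 and 4.45 in knockout Flk1+ and Flk1- cells. The ratio of Hbb-b2 may thus rest on a base level of its probe set and cannot be set against the others. Hba-a1 was at 4.78 in control Flk1+ cells and at 3.79 and 3.88 in knockout Flk1+ and Flk1- cells. Its ratio may therefore also hold a base level in part. The erythroid genes Klf1, Alas2 and Nfe2 were below the floor in control Flk1+ cells, so no such ratio is given for them.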
